A study of Homo sapiens with 8 samples.

How the data were processed

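The 8 RNA libraries were of the SK-N-AS neuroblastoma line, 4 labelled vehicle and 4 labelled tazemetostat at 1 µM, all after 14 days. Groups and replicate numbers were taken from the labels. The submitters' processing notes name Trimmomatic, FastQC, STAR, featureCounts, DESeq2 and R 4.0.3 without versions for the others, and the builds GRCh38 and hg38. The gene models, the strand setting of the counting and the role of each tool are not given in the sources used here, so genes that overlap or lie antisense to each other cannot be told apart, and paralogues with shared reads are uncertain.

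The authors deposited raw counts per gene for each library, in tables of 16166 genes without normalization. All 16166 genes had at least 10 counts in at least 4 libraries, so low genes had been removed before deposit. The authors' deposited comparison table gives a mean of counts scaled by size factors, a log2 fold change of tazemetostat over vehicle with its standard error, and a p-value with its adjusted form, per the file headers. A further deposited table holds log2 values, which fitted log2(x + 1) with x summing to 1000000 in each library; it was used only for a check of the table itself. No column of per-sample values was left without a sample. Of the gene identifiers 15708 (97.2%) matched GENCODE 29 on GRCh38 without their version numbers, which gave coordinates and gene types, and 23 genes share a symbol with another.

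The counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes passed edgeR's filterByExpr with its minimum count of 10 (15983 genes, 183 left out), libraries were scaled by TMM, and the quasi-likelihood F test with robust estimation compared tazemetostat with vehicle, with no covariate. P-values were adjusted by Benjamini-Hochberg and called below 0.05, and changes of at least 2-fold were also counted. The standard error of a log2 fold change is its size divided by the square root of F. CPM values are TMM-scaled and given as mean ± SD over 4 libraries, except for silent genes and the check of the deposited log2 table, where library totals were used. For a gene without counts in a group, the fold was computed against a floor of 3 counts over that group. Such a fold is somewhat higher than the lower limit of the two-sided counting interval. Counting intervals at 95% are exact binomial intervals of the summed counts; they and the floors cover counting error only, since reads without molecular identifiers are not independent molecules.

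Of 30 gene lists fixed beforehand, 27 had at least 5 tested members. These were tested against all other genes with limma's camera on voom log2 CPM with a preset correlation of 0.01 and again with an estimated correlation. limma's fry, which tests a list against no change, was also run and no call rests on it. Genes were named by a rule: the 10 rising and 10 falling genes with the largest log2 fold change among called genes with a mean log2 CPM of at least 1, a symbol and no overlap between groups, up to 4 called members of each list with the smallest p, and 21 genes of interest whatever their values; some of these are not reported here. A gene was called silent in a group with at most 3 counts in each of its libraries and expressed with at least 1 CPM in each library of the other.

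Replicates were compared before averaging: the chi-square per gene between libraries of a group was 1.62 to 2.12 over genes with at least 20 summed counts. This lay above the value of 1 for counting noise, and no files were identical. Each library counted as 1 replicate, as labelled. These checks cannot tell separate cultures from several libraries of a single culture. The first principal component separated the groups and held 92.5% of the variance. On the second, which held 1.6%, vehicle replicate 2 lay at −26.75 and the other vehicle libraries at 7.38 to 10.8. On simulated counts of 15983 genes for this comparison, 15680 passed the filter. Filter and test together recovered 18% of genes changed 1.1-fold, 48% at 1.25-fold, 80% at 1.5-fold and 88% at 2-fold (50 genes each). There were 8 false calls among 15487 unchanged genes. Changed genes that the filter removed counted as missed. The simulation changed only 200 genes, as many up as down, whereas 12090 were called in the data. Its adjusted threshold was therefore stricter, and these shares do not give the recovery in the real comparison. Nor can the false calls show errors of scaling when most genes change.

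Alternatives tried were DESeq2's Wald test, limma-voom, median-ratio, library-size and upper-quartile scaling, other low-count filters, a stricter threshold of 0.01, the replicate number as a block, removal of mitochondrial genes, and leaving out each library in turn. Fixed variation, a test against a 2-fold change and other limits for silent genes were added later.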

Results

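SK-N-AS is an established human neuroblastoma cell line, and tazemetostat is a small-molecule inhibitor of EZH2, the catalytic subunit of the polycomb repressive complex PRC2, which places a repressive methyl mark on histone H3. Total RNA was sequenced from cells kept for 14 days in vehicle (4 libraries) or in 1 µM tazemetostat (4 libraries), and the deposited tables give a raw count per gene. The libraries held 20358976, 17294022, 19865647 and 20703615 counts in vehicle and 16864129, 17293967, 16703550 and 17046354 after tazemetostat. The labels call the 4 libraries of each group biological replicates but name no culture or day for any of them. The p-values of single genes below therefore rest on the spread between these libraries. Those of camera compare the genes of a list with other genes, and the later tests of PRC2 targets and neighbours also take genes as units. The series title concerns lineage plasticity and the response to antibodies against the ganglioside GD2, and the comparison asks which genes differed after prolonged EZH2 inhibition.

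Tazemetostat was followed by a transcriptome-wide difference in which the largest rises were in genes with few or no counts in vehicle. IGF2BP1, an RNA-binding protein of fetal tissues, went from 0.0534 ± 0.0418 to 192.9 ± 3.28 CPM (TMM-scaled counts per 1000000; SD, n = 4 in each group). POSTN, a secreted matrix protein, had no count in any vehicle library and 49.7 ± 2.21 CPM after tazemetostat, which was at least 1250-fold higher when the floor was set at 3 counts over the vehicle group. By the same floor SLFN11, a gene linked to sensitivity to DNA-damaging drugs, was at least 910-fold higher, the kinase gene PRKD1 at least 620-fold and the matricellular factor CTGF at least 462-fold. For POSTN, SLFN11, PRKD1 and CTGF the lower limits of the 95% counting intervals were lower, at 1020, 740, 504 and 375. Among the largest falls, the stress-induced cytokine gene GDF15 fell from 312.1 ± 6.79 to 6.20 ± 0.495 CPM, 50.3-fold lower, and the inhibin subunit gene INHBE was 30.0-fold lower.

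BIRC3, an inhibitor of apoptosis induced by NF-κB, fell from 22.7 ± 1.40 to 0.683 ± 0.171 CPM and the stress-induced cofactor NUPR1 from 29.8 ± 1.88 to 1.18 ± 0.309 CPM. FGF21 and IL1A kept only 3 and 2 counts over the 4 tazemetostat libraries, and their ratios of tazemetostat to vehicle lay between 0.000794 and 0.0113 and between 0.000785 and 0.0237 by 95% counting intervals. In all, 12090 of 15983 tested genes changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 6216 upward and 5874 downward. Rises made up 51.4% of the calls, a share that the scaling sets: it was 58.1% with upper-quartile factors and 60.5% with library size alone. Of the 3357 genes that changed at least 2-fold, 2232 rose and 1125 fell, or 66.5% upward, and among protein-coding genes the split was 1811 to 875. The groups did not overlap for 10987 genes (68.7%), against 2.86% by chance. The biological coefficient of variation was only 2.42%, low for separate cultures, and if the 4 libraries of a group came from a single culture, the SDs and p-values leave out the spread between cultures. With the variation fixed at 0.2 the count of changed genes was 6388, and tested against a 2-fold change it was 2587. Mitochondrial transcripts took 3.17 to 3.43% of the counts in vehicle and 4.10 to 4.44% after tazemetostat.

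**Figure D1:**
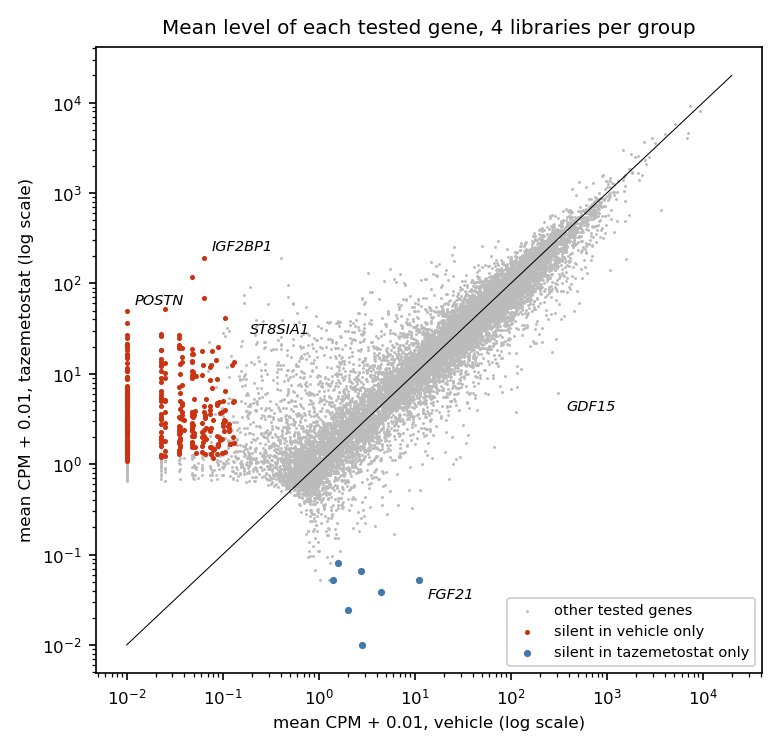
Mean CPM of each tested gene in vehicle (horizontal axis) and after tazemetostat (vertical axis), both on log scales with 0.01 added, 4 libraries per group; the line marks equal levels. Red points are the 355 genes silent in vehicle and expressed after tazemetostat, and blue points the 7 genes with the opposite pattern.

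ST8SIA1, which encodes the GD3 synthase that opens the pathway to GD2, rose from 0.149 ± 0.121 to 23.2 ± 1.81 CPM (SD, n = 4 in each group). Its log2 fold change was 7.25 (SE 0.19, adjusted p = 3.2e-72), a 152-fold ratio resting on 11 counts in the vehicle group, with a 95% counting interval of 88.8 to 320. All 4 tazemetostat libraries lay above all 4 vehicle libraries, and an exact two-sided permutation test gave p = 0.0286, the smallest that 70 arrangements allow. ST3GAL5, the GM3 synthase acting just before it, rose from 2.03 ± 0.379 to 13.5 ± 1.24 CPM. B4GALNT1, which completes GD2 from GD3, had 17.0 ± 1.13 CPM in vehicle and 18.8 ± 1.44 CPM after tazemetostat and did not pass the test (log2 fold change 0.15, SE 0.073, adjusted p = 0.056).

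The B4GALNT1 value sat at the threshold. It passed with scaling by library size alone (log2 fold change 0.25), by upper-quartile factors (0.22) or by median ratios, and with both other low-count filters, and leaving out vehicle replicate 2, vehicle replicate 4 or tazemetostat replicate 4 gave adjusted p = 0.037, 0.042 and 0.013. The identifiers that follow are those deposited with the counts, and the coordinates are those of GENCODE 29 on GRCh38. ST8SIA1 (ENSG00000111728.6) lies on the minus strand of chromosome 12 at 22063773 to 22437041. B4GALNT1 (ENSG00000135454.9) lies on the same strand of chromosome 12 at 57623410 to 57633355. ST3GAL5 (ENSG00000115525.12) lies on the minus strand of chromosome 2 at 85837120 to 85905199. Over the ganglioside synthesis list, 6 of 15 measured members rose, 6 fell and 3 did not pass. Adjusted over the list alone, 7 rose and 7 fell. ST8SIA3, a related sialyltransferase, had no vehicle count and 6.87 ± 0.985 CPM after tazemetostat, at least 173-fold higher, whereas B4GALT6, a lactosylceramide synthase, fell 3.05-fold to 87.7 ± 6.55 CPM. As a set the list did not differ from other genes (camera adjusted p = 0.86); the test leaned downward, while the median log2 fold change was 0 and the mean 1.22.

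Among genes for ganglioside breakdown and sialic acid supply, 8 of 17 fell and 2 rose, against 8 and 1 adjusted over the list alone; scaling by library size alone gave 8 and 5, with a median log2 fold change of −0.03 in place of −0.13. The lysosomal sphingolipid activator gene PSAP fell from 1288 ± 10.5 to 487.3 ± 5.38 CPM. CMAHP, a pseudogene of a sialic acid hydroxylase, was 5.99-fold lower. The list was called downward (camera adjusted p = 0.042), a call lost with an estimated correlation between genes (adjusted p = 0.10 with an estimated correlation) and with a filter of at least 1 CPM in 4 libraries (adjusted p = 0.055).

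**Figure D2:**
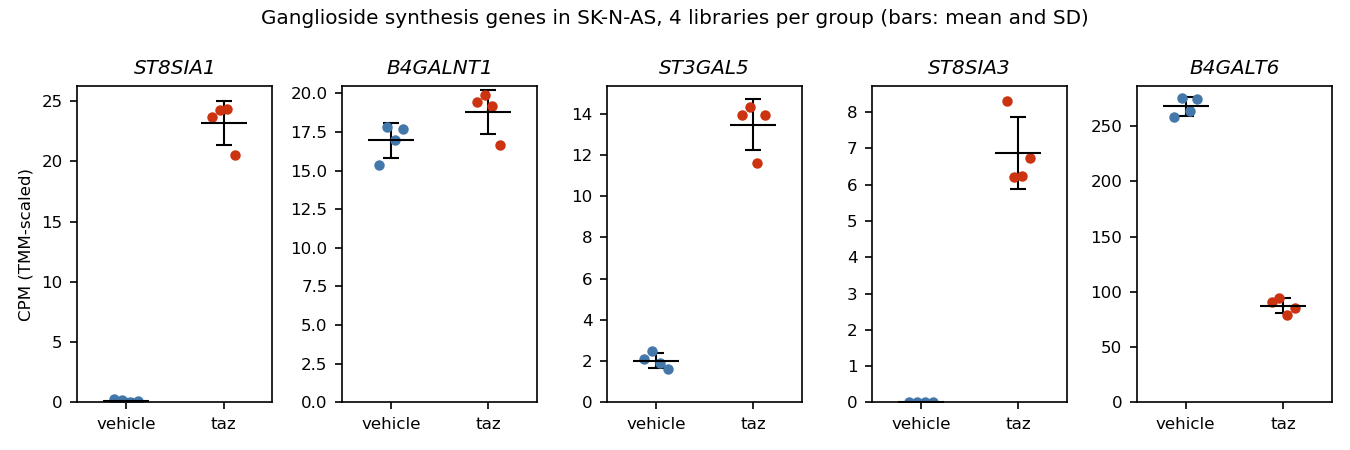
CPM (vertical axes, each from 0) of 5 ganglioside synthesis genes in 4 vehicle (blue) and 4 tazemetostat (red) libraries, with the mean and SD in black. ST8SIA1 went from 0.149 to 23.2 and ST3GAL5 from 2.03 to 13.5, while B4GALNT1 had 17.0 and 18.8.

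Neuronal structure and synapse genes moved upward: 29 of 37 rose and 6 fell, and the list was called by camera (adjusted p = 5.3e-06; adjusted p = 0.024 with an estimated correlation). STMN2, a growth cone protein, rose from 6.38 ± 0.628 to 104.7 ± 2.36 CPM, the tubulin gene TUBB2B from 4.82 ± 0.686 to 105.4 ± 3.96 CPM and the kinesin gene KIF5C 3.28-fold. DPYSL3, also a neuronal cytoskeleton gene, fell 1.89-fold. Adrenergic transcription factors, the regulators of the sympathetic state of neuroblastoma, split: 16 of 25 rose and 8 fell, and the list was not called (camera adjusted p = 0.14). HAND1 rose 12.2-fold and SATB1 30.4-fold. GATA3 rose 1.26-fold and ISL1 1.12-fold. In the other direction PHOX2A fell 1.68-fold, HAND2 1.18-fold and INSM2 2.20-fold.

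The catecholamine and chromaffin genes likewise went both ways, with 10 of 22 rising and 8 falling (camera adjusted p = 0.86, leaning downward; median log2 fold change −0.01, mean 0.21). DBH, which makes noradrenaline, rose from 50.4 ± 3.45 to 261.9 ± 2.92 CPM. DDC, the decarboxylase that acts before it, fell 6.09-fold, and the secretory granule genes VGF and SCG2 fell 3.01-fold and 2.17-fold. In these 3 lists, and in the mesenchymal, NOTCH and neural crest lists below, the counts adjusted over the list alone were equal to those over all genes.

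Mesenchymal transcription factors were lower: 24 of 35 fell and 8 rose (camera adjusted p = 0.00021; adjusted p = 0.024 with an estimated correlation). The median log2 fold change was −0.73 while the mean was 0.03. PRRX1, a regulator of the mesenchymal state, fell from 85.8 ± 1.78 to 42.6 ± 2.68 CPM, and the AP-1 members JUNB and FOSL2 fell 3.04-fold and 3.39-fold. IRF1, an interferon regulatory factor, was 4.74-fold lower. NOTCH2 rose from 0.391 ± 0.250 to 189.6 ± 6.64 CPM, 469-fold with a 95% counting interval of 334 to 708, and the repressor SNAI2 rose 9.94-fold.

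Mesenchymal matrix and adhesion genes showed no common direction, with 27 of 52 rising and 22 falling (camera adjusted p = 0.74). VIM, the intermediate filament of mesenchymal cells, fell from 546.5 ± 10 to 236.6 ± 6.54 CPM, CDH2 3.18-fold and ANXA2 2.34-fold. FN1, which encodes fibronectin, rose from 2.92 ± 0.420 to 35.6 ± 3.37 CPM, and the collagen gene COL12A1 from 0.156 ± 0.123 to 75.1 ± 1.54 CPM. NOTCH pathway genes rose in 14 of 20 and fell in 2 (camera adjusted p = 0.0052; adjusted p = 0.048 with an estimated correlation): besides NOTCH2, the receptor gene NOTCH3 was 7.40-fold higher, the ligand gene JAG1 16.4-fold and DLK1 34.0-fold. Of 10 neural crest and Schwann cell genes 5 rose, among them NGFR (2.16-fold) and GAP43 (4.03-fold), and 4 fell, among them NGEF (5.25-fold); the list was not called (camera adjusted p = 0.70, leaning upward; median log2 fold change −0.08, mean 0.09).

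MHC class I antigen presentation genes were lower after tazemetostat, with 19 of 21 falling and 2 rising. B2M, the invariant light chain, fell from 371.0 ± 8.94 to 151.2 ± 6.95 CPM, and the peptide-loading gene TAPBP 2.56-fold. CANX, a chaperone of the same pathway, fell 1.38-fold. The list was called downward (camera adjusted p = 6.6e-05; adjusted p = 0.040 with an estimated correlation). Adjusted over the list alone, the counts were again 19 and 2. Reads of HLA genes can be shared between near-identical copies, so the value of a single HLA gene is uncertain.

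Of 5 measured MHC class II genes 3 rose and 1 fell, and adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.32). HLA-DPA1 had no vehicle count and 5.79 ± 0.961 CPM after tazemetostat, at least 146-fold higher. CIITA, the class II transactivator, rose from 0.373 ± 0.0792 to 1.31 ± 0.256 CPM, and the protease gene CTSS fell 6.10-fold.

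Interferon-stimulated genes fell in 38 of 48 and rose in 5 (camera adjusted p = 4.6e-07; adjusted p = 0.024 with an estimated correlation). The antiviral gene BST2 fell from 220.9 ± 7.40 to 81.8 ± 3.46 CPM, PARP14 2.65-fold and the guanylate-binding protein GBP2 8.93-fold. Inflammatory cytokine and chemokine genes fell in 15 of 24 and rose in 7 (camera adjusted p = 0.020). This call was lost with an estimated correlation (adjusted p = 0.067 with an estimated correlation). CCL2, a monocyte attractant, fell from 271.8 ± 3.45 to 17.5 ± 2.21 CPM, the adhesion receptor ICAM1 12.9-fold, the cytokine LIF 6.71-fold and NFKBIA, the inhibitor of NF-κB, 3.39-fold.

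Ligands for NK cells and checkpoint ligands fell in 13 of 17 and rose in 4 (camera adjusted p = 0.038), with a median log2 fold change of −0.62 and a mean of 0.02. The call was again lost with an estimated correlation (adjusted p = 0.098 with an estimated correlation). CD274, which encodes PD-L1, fell from 14.5 ± 1.28 to 2.96 ± 0.705 CPM, the death receptor TNFRSF10B 3.82-fold and CD47, which restrains phagocytosis, 1.54-fold. For these 3 lists the counts adjusted over the list alone were equal to those over all genes, as they were for the following pair. Complement regulators fell in 7 of 12 and rose in 3 (camera adjusted p = 0.33, leaning downward; median log2 fold change −0.41, mean 0.57). CLU fell 3.70-fold and CFI 2.35-fold, and CD55 rose from 0.229 ± 0.196 to 13.8 ± 0.949 CPM. Other surface targets of neuroblastoma immunotherapy rose in 7 of 16 and fell in 7 (camera adjusted p = 0.70, leaning downward; median log2 fold change −0.03, mean 0.43). DLL3 rose 2.50-fold to 103.4 ± 4.87 CPM, L1CAM fell 1.96-fold and EPHA2 3.47-fold.

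EZH2 itself was slightly lower, at 129.4 ± 2.79 CPM in vehicle and 114.2 ± 3.72 CPM after tazemetostat (log2 fold change −0.18, SE 0.03, adjusted p = 4.9e-08). Its paralogue EZH1 fell 1.51-fold, and the PRC2 core subunit EED rose 1.68-fold. SUZ12 had a log2 fold change of 0.09 and did not pass the test (adjusted p = 0.055), a value that also lay at the threshold: it passed without vehicle replicate 2 (adjusted p = 0.031) or tazemetostat replicate 2 (adjusted p = 0.029), with limma-voom, with each other scaling and with both other low-count filters. The authors' deposited table also calls SUZ12 (adjusted p = 0.0404). Of 13 PRC2 subunits and partners 6 rose, among them RBBP4 (1.48-fold) and MTF2 (1.51-fold), and 5 fell, against 7 and 5 adjusted over the list alone (camera adjusted p = 0.57). Of 22 PRC1 subunits 7 rose and 11 fell, against 8 and 11 adjusted over the list alone (camera adjusted p = 0.57), but 10 rose and 10 fell with library size alone or upper-quartile factors. PCGF5 fell 2.03-fold and CBX8 rose 1.58-fold.

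Genes listed in textbooks as PRC2 targets outside the HOX clusters rose in 34 of 48 and fell in 9 (camera adjusted p = 0.00075; adjusted p = 0.048 with an estimated correlation). PAX5 rose from 0.0969 ± 0.113 to 26.2 ± 1.31 CPM, the nuclear receptor NR2F2 25.8-fold and the cell cycle inhibitor CDKN2A from 39.0 ± 1.07 to 108.2 ± 3.91 CPM, while VASH1 fell 1.87-fold. HOX genes rose in 11 of 16 and fell in 2, or 1 with library size alone or upper-quartile factors. HOXC8 rose 3.09-fold, HOXD8 fell 1.80-fold, and HOXC10 had 1 count over the 4 vehicle libraries and 5.05 ± 0.274 CPM after tazemetostat, a ratio with a 95% counting interval of 68.0 to 15100. For both lists the counts adjusted over the list alone were equal. The lists held 101 genes outside HOX and 39 HOX genes, and the remaining members were not measured. A member silent in vehicle was measured only if tazemetostat libraries expressed it, so it could not count as a fall. Members silent in both groups were dropped, which raises the share that rose, and the camera calls share this limit. It also applies to other lists with members not measured. The HOX call was weak (camera adjusted p = 0.045) and was lost with an estimated correlation (adjusted p = 0.19 with an estimated correlation), with library size alone (adjusted p = 0.099) and without vehicle replicate 3 (adjusted p = 0.054).

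Genes with at most 3 counts in each library of a group were set apart from the rest. There were 355 such genes that were silent in vehicle and had at least 1 CPM in all 4 tazemetostat libraries, and 7 with the opposite pattern. Both counts depend on the limits, which were chosen after the data were seen: with no count allowed in the silent group they were 151 and 1, at 5 CPM 104 and 1, and at 0.5 CPM 523 and 27. The 7 were S100A14, FFAR2, FGF21, IL1A, CSF2, LTB and RHAG, of which all but FGF21 and IL1A were chosen after their values were seen. The 355 genes had a median of 3.19 CPM after tazemetostat, and 64 of them reached 10 CPM. The deposited tables hold only genes with at least 10 counts in at least 4 libraries, so a gene silent in either group is listed only where the other group expressed it.

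All 45 proliferation genes rose (camera adjusted p = 3.4e-18; adjusted p = 0.0021 with an estimated correlation). MKI67, a marker of cycling cells, rose from 211.5 ± 6.57 to 415.4 ± 13.3 CPM, the replication factors PCNA and MCM3 2.59-fold and 1.96-fold, and the ribonucleotide reductase gene RRM2 2.98-fold. Cell cycle arrest and senescence genes went both ways, with 10 of 19 rising and 7 falling (camera adjusted p = 0.43): CDKN1A fell from 25.5 ± 0.923 to 13.2 ± 0.457 CPM and SESN2 5.34-fold, and IGFBP3 rose 18.3-fold. Sterol synthesis genes rose in 19 of 20 with none falling (camera adjusted p = 3.2e-07; adjusted p = 0.012 with an estimated correlation), among them the isomerase gene IDI1 (3.12-fold).

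Stress, apoptosis and unfolded protein genes fell in 15 of 19 and rose in 4 (camera adjusted p = 1.8e-05; adjusted p = 0.024 with an estimated correlation). ASNS, the asparagine synthetase induced by amino acid shortage, fell from 508.6 ± 6.82 to 60.3 ± 3 CPM, TRIB3 8.17-fold, DDIT4 7.05-fold and XBP1 3.35-fold. Hypoxia and glycolysis genes fell in 13 of 18 and rose in 3 but were not called as a list (camera adjusted p = 0.054). With library size alone 10 fell and 6 rose, and with upper-quartile factors 10 and 4. Without vehicle replicate 1 or tazemetostat replicate 3 the adjusted p rounded to 0.05 and passed. VEGFA fell from 299.2 ± 6.85 to 65.0 ± 1.21 CPM and HK2 1.63-fold, and LDHA rose 1.57-fold. In these 5 lists the counts adjusted over the list alone were equal to those over all genes, and the mitochondrial share of counts was higher in the same 4 tazemetostat libraries.

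Few of the listed markers of other cell types were measured, though PTPRC among them was well expressed in both groups. Of the leukocyte markers 4 were measured: CORO1A and CD14 rose 2.41-fold and 3.19-fold, 1 did not pass, and PTPRC, which encodes CD45, fell from 324.6 ± 5.05 to 183.8 ± 0.793 CPM. The 3 measured endothelial markers all rose but stayed low, VWF reaching 0.983 ± 0.352 CPM and ESAM 0.867 ± 0.2 CPM. Of 2 epithelial markers KRT8 rose 3.45-fold to 51.4 ± 1.74 CPM and the other did not pass over all genes; adjusted over the list alone 1 rose and 1 fell. Of 5 muscle markers 4 rose (camera adjusted p = 0.056; 0.05 when rounded, and passing, without vehicle replicate 1 or tazemetostat replicate 3), TNNT1 from 3.97 ± 0.950 to 25.9 ± 1.44 CPM and TNNT2 from 1 count over the vehicle group to 3.33 ± 0.391 CPM, a ratio with a 95% counting interval of 44.7 to 9970. Of 5 cancer testis antigen genes 4 rose and 1 fell (camera adjusted p = 0.12): PRAME rose 1.40-fold, SSX1 from 0.0557 ± 0.0491 to 3.38 ± 0.566 CPM, and CTAG2 fell 1.33-fold. Except for the epithelial markers, these lists gave equal counts adjusted over the list alone.

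**Figure D3:**
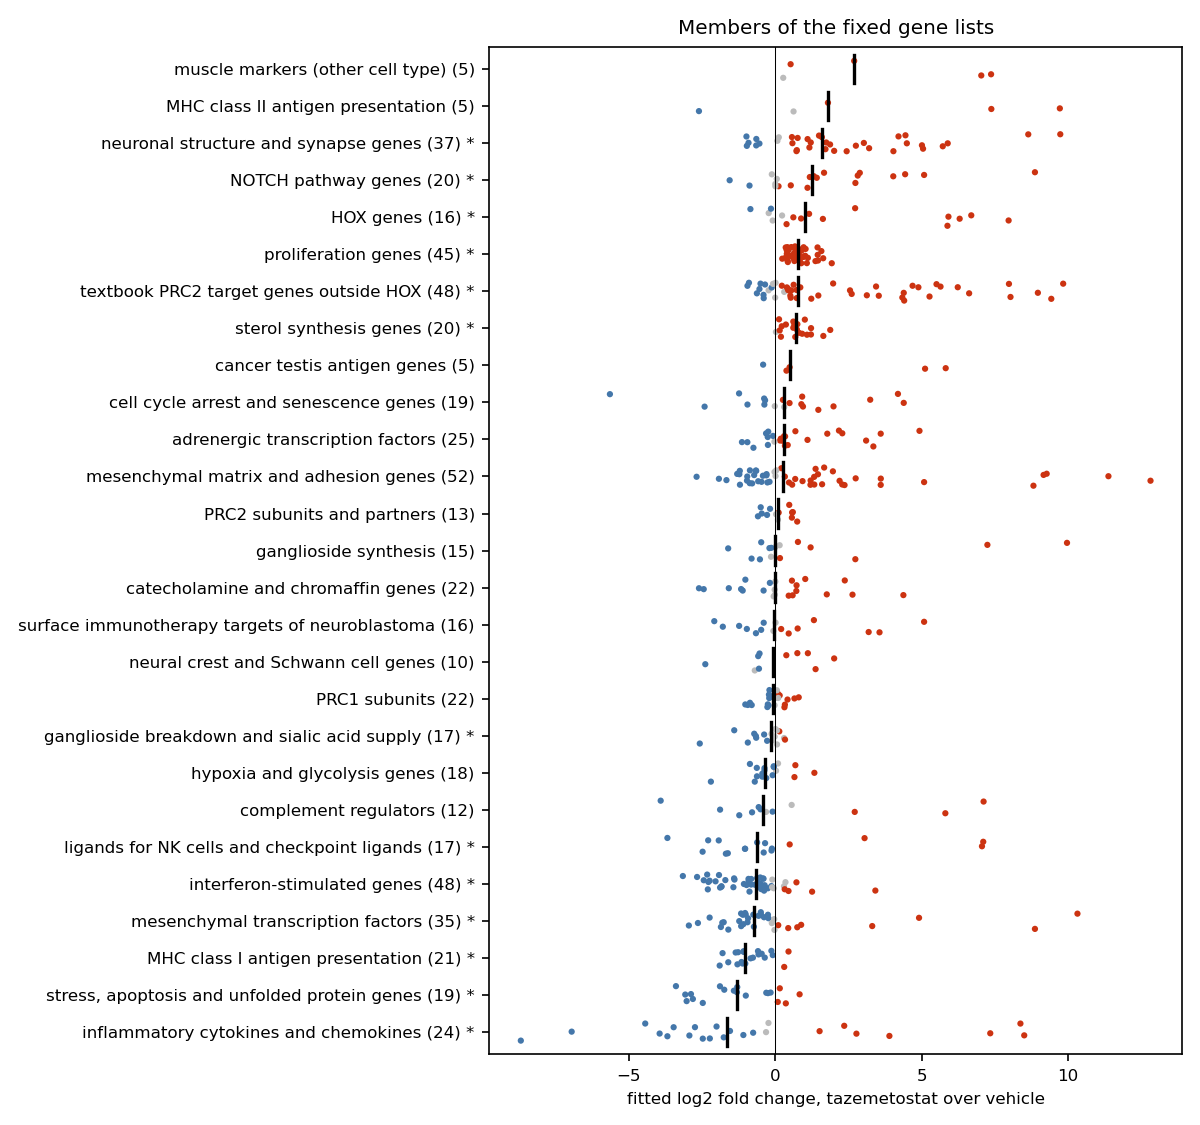
Fitted log2 fold change of tazemetostat over vehicle (horizontal axis) for each measured member of the 27 fixed lists with at least 5 of them, one list per row with its number of measured members; red and blue points passed the test upward and downward, grey points did not, and black bars are list medians. The 13 lists with an asterisk were called by camera, and points of genes without counts in a group depend on the fit's prior count.

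In all 13 of 27 lists were called, 6 upward and 7 downward, and 9 of them were also called with an estimated correlation between genes. Some called lists share members, such as IRF1, ICAM1 and NOTCH2, so the calls are not independent. The authors' deposited table of the same comparison lists 11872 genes at an adjusted p below 0.05, 6196 higher and 5676 lower after tazemetostat. Among the 15983 genes tested in both, calls were shared for 11771, all in the same direction, with 319 called only in the fit made here and 52 only in the authors' deposited table. The authors' remaining calls were of genes left out by the low-count filter used here. For ST8SIA1 the authors' deposited table gives a log2 fold change of 7.28 and for B4GALNT1 0.16, with adjusted p values of 7.92e-61 and 0.0609. Changes are relative to the bulk of genes as TMM sets it; library size alone moved the median log2 fold change of all genes by 0.101.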

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

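Libraries of each group of 4 were compared for the genes named above, the library totals and the mitochondrial share, and 14 of 224 groups held a library apart from its 3 companions, where about 11 are expected by chance. In tazemetostat replicate 3, ST3GAL5 had 11.6 CPM (13.9 to 14.3 in the other libraries of the group), SNAI2 8.04 CPM (7.05 to 7.12), NOTCH3 128 CPM (120 to 121), NGFR 109 CPM (103 to 104) and IL1A 0.116 CPM (0 in the others); this library held 5 of the 14. The other tazemetostat value apart was DDC at 45.3 CPM in replicate 2 (48.1 to 48.2).

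Among vehicle libraries, replicate 1 stood apart for NOTCH2 at 0.764 CPM (0.239 to 0.312), CIITA at 0.255 CPM (0.401 to 0.419) and TNNT2 at 0.0509 CPM (0 in the others). Vehicle replicate 2 stood apart for PARP14 at 161 CPM (156 to 157), EZH2 at 134 CPM (128 in the others, as rounded) and HOXC10 at 0.0599 CPM (0 in the others). In vehicle replicate 3, TUBB2B had 3.80 CPM (5.09 to 5.21) and PSAP 1300 CPM (1280 in the others, as rounded). The values of IL1A, HOXC10 and TNNT2 rest on 1 or 2 counts.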

How the results depend on the processing

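Alternatives were set before the data were examined, except fixed variation, the test against a 2-fold change and the limits for silent genes, which were chosen after seeing the data. The count of changed genes ran from 11099 to 12172 over the planned settings and from 11801 to 11896 with a library left out; ST8SIA1 stayed called, with a log2 fold change of 6.84 to 7.66 in the latter. The called lists numbered 12 to 15 with a library left out and 9 with an estimated correlation. Fixing the variation at 0.2 gave 6388 changed genes, fixing it at 0.1 gave 9903, and testing against a 2-fold change gave 2587; the larger assumed spread and the stricter null make fewer calls by construction. Library size alone raised the share of rises from 51.4% to 60.5%, and 14 called genes were called in the opposite direction. The mesenchymal matrix list, not called, had its set test turn downward under library size alone (median 0.37, adjusted p = 0.99; the cause was not tested). Medians near 0 of the catecholamine, neural crest, surface target and PRC1 lists, none called, turned positive under it.

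Genes silent in vehicle numbered 151 when no count was allowed, 104 at 5 CPM and 523 at 0.5 CPM, and those silent in tazemetostat 1, 1 and 27; tighter limits keep fewer genes by construction and looser ones more. Same-numbered libraries did not deviate together over all genes (correlations −0.014 to 0.013), so no pairing by number was seen. A pairing that touched few genes could be missed. The replicate block gave 11962 changed genes, 11957 of them shared. The block moved no call of a named gene or list.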

Other observations

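The tests of library depth, PRC2 targets, neighbours without overlapping genes, culture state and the deposited log2 table were chosen after the results were seen; those of the other splits, chromosome copies and neighbouring genes were set before theirs were. The genes named in this part were chosen after their values were seen. Among the 355 genes silent in vehicle were receptors and regulators with known roles in tumour cells. EPHA3, an ephrin receptor, had 3 counts over the 4 vehicle libraries and 122 ± 2.32 CPM after tazemetostat (SD, n = 4). ABCB1, the drug efflux pump P-glycoprotein, had 7 counts and then 42.7 ± 2.88 CPM, the receptor MET 3 counts and 19.7 ± 1.6 CPM, and SMARCA2, an ATPase of the SWI/SNF remodelling complex, 1 count and 13.8 ± 1.42 CPM. MEF2C, a muscle and neural transcription factor, had 1 count and 13.7 ± 1.14 CPM.

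Several genes of this class were neighbours among the genes with deposited counts. The desmosomal cadherin genes DSC3, DSC2 and DSG2 on chromosome 18 (30990008 to 31549008, GRCh38) were all silent in vehicle and reached 11.1, 16.9 and 72.3 CPM. The collagen genes COL4A1 and COL4A2, which lie side by side on chromosome 13 (110148963 to 110513209), reached 21.4 and 19.9 CPM. DLX5, DLX6 and DLX6-AS1 on chromosome 7 (96955141 to 97024950) also belonged to the class, though DLX6 and DLX6-AS1 overlap, as do the annotated spans of COL4A1 and COL4A2, and so did PTGS2 and PLA2G4A on chromosome 1 (186671791 to 186988981).

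The 12090 changed genes were set against the other ways to split the libraries: 1 of 35 splits of the 8 libraries into 4 and 4, the real one, called as many. The other 34 splits called at most 0 by edgeR, and at most 385 genes at an unadjusted p below 0.05, against 12293 in the real one. The other splits each mixed libraries of both groups, which widens the spread within a group and leaves few calls. The real split was 1 of only 35, so this count alone does not exclude chance assignment of libraries to the groups. Anything else that differed between the groups is not excluded either.

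For the 355 genes silent in vehicle against 7 silent after tazemetostat, depth argues the wrong way: the vehicle libraries, where more genes were silent, were deeper, by a ratio of mean totals of 1.15. A different cell line with other chromosome copies in either group is argued against by the chromosome medians, since the largest deviation over 23 chromosomes was 0.15 in log2 fold change. Release of PRC2 repression is a candidate explanation: 9 of 319 class members were in the HOX and PRC2 target lists, against 25 of 5419 genes of similar level. The odds ratio was 6.26 (two-sided Fisher exact test, 95% interval 2.55 to 14, p = 6.9e-05). The genes compared were matched on level and not on being silent in vehicle. The ratio therefore cannot tell PRC2 release from another cause that turns on silent genes. Release over domains of neighbouring genes is another candidate explanation. Adjacent pairs were genes next to each other among 15685 deposited genes with coordinates, so genes without deposited counts may lie between them. There were 49 such pairs against a median of 7 and a maximum of 22 in 100000 random draws (permutation p = 1e-05). This p is the smallest the draws can give. Matched on level, 39 pairs stood against a maximum of 20. Without the 8 pairs of overlapping genes, whose reads cannot be told apart here, 41 pairs stood against a maximum of 19. Related genes side by side also add to the count. A clone of the same karyotype and an effect of culture unrelated to EZH2 stay open, and only 9 of the 319 genes were on the PRC2 lists.

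The stress and interferon lists were lower and the proliferation list higher after tazemetostat. A difference in culture state or day, such as denser or more starved vehicle cultures, could give this pattern as well as the drug. The highest correlation of the deviations of a same-numbered pair of libraries was 0.013, so no shared day was seen, but shared days would not exclude a difference in density or feeding between the groups. Values here that can move with culture state, such as ASNS (508.6 CPM in vehicle, 60.3 CPM after tazemetostat), do not separate it from the drug. Drug and culture cannot be told apart for these genes, nor for the stress-induced genes GDF15 and NUPR1. The labels name no culture for any library, so the same limit holds for every other list and gene. This includes the mesenchymal factor, MHC class I, cytokine, NK and checkpoint ligand and sterol lists.

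In the deposited log2 table the levels of genes did not follow their counts: the vehicle libraries had a mean back-transformed value of 10.1 for VIM and 1490 for ZZZ3, against 528 and 77.2 CPM of library totals. A candidate explanation is that gene lengths were taken in another row order. The divisor implied for each gene correlated across 15247 genes with the genomic span of the gene in the same row of the count tables (Spearman 0.986), not with the gene's own span (−0.026), and matched it within 5% of a common scale for 91.1% of genes, against 2.0% for its own span. Within a gene the divisor varied little between libraries (median coefficient of variation 1.02%), so the table's differences between groups are affected far less than its levels across genes. No biological explanation was tested.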
